A study of Mus musculus with 12 samples.

How the data were processed

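Per the labels' protocols, satellite cells were isolated from heterozygous mice in which ZsGreen is expressed from the Pax7 locus. Muscle was dissociated with collagenase and dispase, and fluorescent cells were sorted with gates set for each age against wild-type muscle. The fetal cells came from forelimbs and hindlimbs of 4 mice at E17.5. The later stages were hindlimb cells, from 6 mice at postnatal day 21, 8 mice at 2 to 3 months and 8 mice aged over 1 year. RNA was amplified from 100 ng with the Ambion WT Expression kit, labelled with biotin and read on single-colour Affymetrix arrays. Whether the 3 replicates of a stage were separate pools of animals is not stated, so the p-values measure only the spread between these samples, which may be technical.

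Per the submitters' processing notes, the arrays were summarised by RMA in Affymetrix Expression Console 1.2.1.20. The deposited values are on the log2 scale and were used without further transformation. The genome build is not given. No value column was left unused. Scanner files were not used, so background correction and normalization were taken as given.

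Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 were not named here. Probe sets with 1 symbol were reduced to 19938 genes by taking the probe set with the highest mean, and 999 genes had several. Genes with probe sets called in opposite directions numbered 0 in adolescent against fetal, 2 in adult against adolescent, 0 in aged against adult and 9 in adult against fetal. The lowest array median was 6.13 and the highest 6.29. Deviations of adolescent and adult arrays from their stage means correlated between equal replicate numbers at 0.362, 0.317 and 0.239. Replicates 2 and 3 also correlated across numbers (0.293 and 0.240), as did adult replicate 1 with aged replicate 2 (0.447). The labels state no pairing, and the main fit has none. With replicate number as a block 3458 genes passed in adult against adolescent, and 3941 without.

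All 12 arrays entered a single linear model with a mean for each stage, fitted with limma 3.58.1 in R 4.3.3 with moderated variances and 8 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over 19938 genes, and rose or fell refers to genes that passed. A 2-fold change is a log2 difference of 1. Differences among the 4 stages were tested with limma's F-test. With 3 arrays against 3, an exact rank test cannot give a p under 0.1, and 10% of genes are expected to show no overlap by chance.

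The comparisons, the 33 gene lists, the rule for naming genes and the alternatives were set before the data were examined. Of 896 names in the lists 836 were matched to measured genes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, and p was adjusted over all lists and comparisons. Camera with an estimated correlation and the rotation test fry were alternatives. Members were also adjusted over their own list alone.

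Genes named are the 10 largest rises and falls among genes that passed with no overlap between groups and a mean of at least 6 in the higher group, up to 4 members of each list with the smallest p, and 13 fixed genes. Predicted genes, RIKEN clones, small RNAs, olfactory and vomeronasal receptors and segments of antigen receptor genes were left out of the largest changes. H19 was among the fixed genes but was not analysed here. Jchain and the receptor genes were followed array by array after their values were seen.

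The alternatives were repeated quantile normalization, centring of each array on its median, a floor at 6, filters on dim genes, the mean of a gene's probe sets, all probe sets, a fit of the 2 stages compared, a trended and robust variance, array weights, replicate number as a block, a test against a 1.5-fold change, other list tests, Spearman's correlation and leaving out each array. For a comparison, results without an array are given only for arrays of the 2 stages compared.

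The methods were first run on simulated arrays of 19938 genes, of which 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. At 4-fold 66 of 66 changed genes were recovered in each comparison. At 2-fold 58, 58, 55 and 54 of 67 were recovered in adolescent against fetal, adult against adolescent, aged against adult and adult against fetal, and at 1.5-fold 25, 28, 32 and 35 of 67. False calls numbered 8, 5, 11 and 6. A shifted list of 42 genes was called in each, and 0 lists sharing no gene with it were called by camera. Other splits of the real arrays called 6 to 21 lists. There list genes correlate and part of the stage difference stays, so this 0 is not taken to carry over.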

Results

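Gene expression was measured on 12 single-colour microarrays of mouse satellite cells, the muscle stem cells that carry the transcription factor Pax7. The cells had been sorted for the green fluorescence of a Pax7 reporter. They came from 4 stages with 3 arrays each: fetal (E17.5), adolescent (postnatal day 21), adult (2 to 3 months) and aged (over 1 year). Array medians lay between 6.13 and 6.29 on the log2 scale, and the number of arrays limits the precision. Arrays of a group correlated with a median Pearson r of 0.993 across genes (0.972 to 0.999 over 12 pairs), against 0.964 between groups (0.905 to 0.986 over 54 pairs). The first principal component held 64.4% of the variance and the second 15.4%. For 11 of 12 arrays the nearest array came from its own group, and adult replicate 1 lay nearest to adolescent replicate 2 (r = 0.985).

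**Figure D1:**
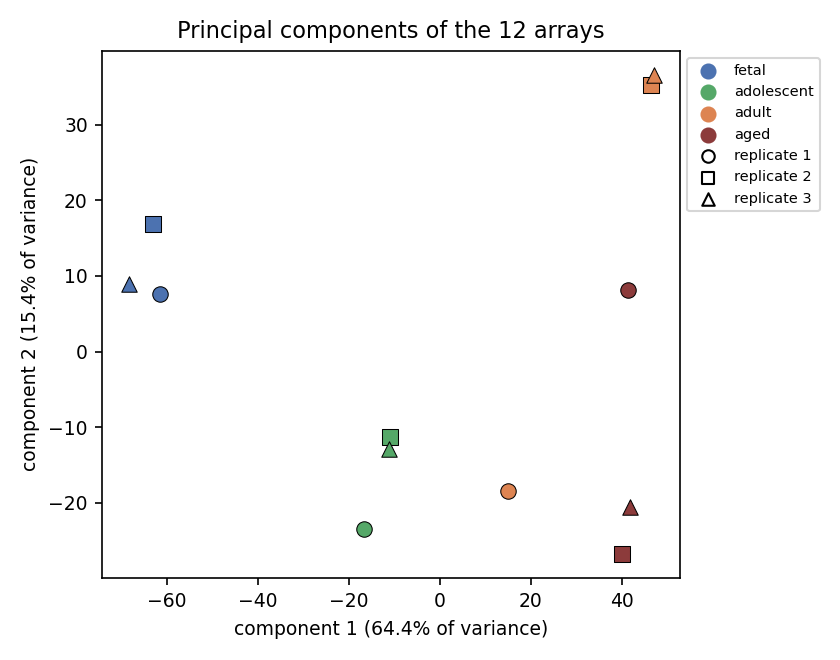
The 12 arrays on the first (64.4% of variance) and second (15.4%) principal component of the gene-level log2 values, with colour for stage and symbol for replicate number. Fetal arrays lie at the low end of the first component, and adult replicate 1 lies apart from adult replicates 2 and 3.

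Olfactory and vomeronasal receptor genes, which serve smell and pheromone detection, were used as a measure of background. Their mean over 1193 probe sets was 4.47 on adult replicate 2, 4.50 on adult replicate 3 and 4.31 on aged replicate 1, and 3.79 to 3.92 on the other 9 arrays. Mki67, a marker of cycling cells, stood at 9.28 on adult replicate 1, 6.58 on adult replicate 2 and 6.44 on adult replicate 3. Of 19938 genes, 8293 (41.6%) differed among the 4 stages by limma's F-test. Without adult replicate 1 that count was 14192.

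**Figure D2:**
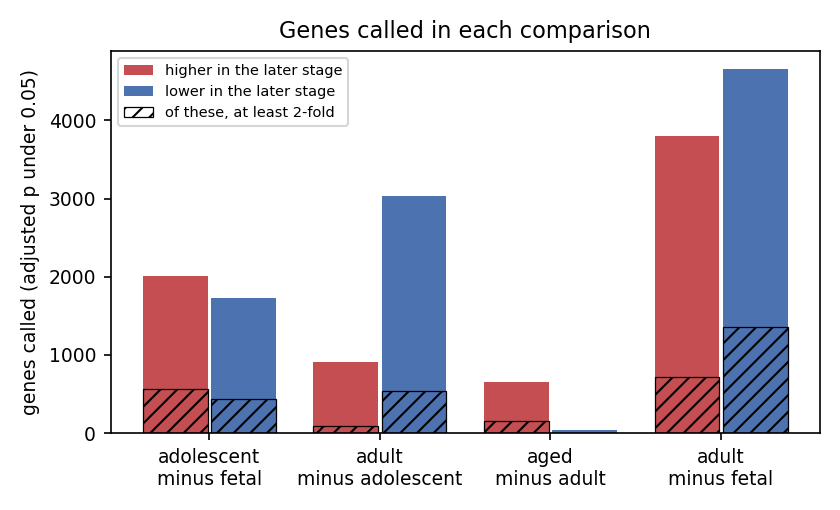
Genes higher (red) and lower (blue) in the later stage of each comparison at an adjusted p under 0.05, with the hatched part at least 2-fold. Counts run from 697 in aged against adult to 8465 in adult against fetal.

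The comparison of adolescent with fetal cells spans late gestation to postnatal growth. Esr1, an oestrogen receptor, was 24.0-fold higher in adolescent cells (log2 difference 4.58 ± 0.11, SE pooled over all 4 stages, n = 3 each, as for all genes here). Mstn (myostatin) was 24.3-fold lower (-4.60 ± 0.09). Other large rises were those of Pvalb (4.37 ± 0.35), a calcium buffer of fast fibres, Nr1d1 (3.88 ± 0.12), a repressor of the circadian clock, Ret (3.72 ± 0.13) and Gpx3 (3.69 ± 0.09). Retnla (4.11 ± 0.38, a lower bound from a fetal 3.60 at the receptor signal), Filip1l (3.98 ± 0.18), Erfe (3.85 ± 0.22), Gal (3.71 ± 0.30) and Medag (3.66 ± 0.15) rose as well. Large falls were seen in Cpa3 (-4.30 ± 0.21), a mast cell protease, Fbn2 (-4.04 ± 0.13) and Vcan (-4.01 ± 0.17), matrix genes, Igf2bp3 (-3.98 ± 0.10), an oncofetal RNA-binding protein, and Nrk (-3.83 ± 0.12). Tnc (-3.89 ± 0.31), Agtr2 (-3.87 ± 0.13), Nnat (-3.74 ± 0.13) and Parm1 (-3.68 ± 0.11) also fell.

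In all, 3739 genes passed (2008 higher and 1731 lower in adolescent cells), and 991 of them differed at least 2-fold (559 higher and 432 lower). The groups did not overlap for 8303 genes (41.6%), where chance gives 10%. With replicates 2 and 3 of each stage averaged into 1, which was tried after their closeness was seen, 1472 genes passed. Without a single fetal or adolescent array the count ran from 2690 to 3330.

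Of 25 satellite cell identity genes, 14 rose and 2 fell (14 and 3 adjusted over the list alone), with rises of Chrdl2 (2.99 ± 0.19) and Sdc4 (2.19 ± 0.13). The identity list shifted up (median 0.49, adjusted p = 5.17e-06, adjusted p = 0.195 with an estimated correlation). Pax7 itself rose (0.50 ± 0.10), as did the myogenic factors Myf5 (0.78 ± 0.12) and Myod1 (0.79 ± 0.11), while Pax3 (0.19 ± 0.11) and Myog (0.74 ± 0.44) did not pass. Of 29 genes tied to satellite cell quiescence, 18 rose and 2 fell (21 and 2 adjusted over the list alone), among them Calcr (1.86 ± 0.09), the calcitonin receptor, Rgs5 (3.02 ± 0.22) and Foxo1 (1.05 ± 0.10), and Spry1, a brake on growth factor signalling, rose by 0.83 ± 0.09. The quiescence list shifted up (median 0.63, adjusted p = 4.63e-11, adjusted p = 0.0549 with an estimated correlation). Of 30 muscle commitment genes, 4 rose and 11 fell (6 and 12 adjusted over the list alone), led by Myh3 (-3.67 ± 0.24), the embryonic myosin heavy chain, and Tnni1 (-1.93 ± 0.15), the troponin of slow fibres. The commitment list shifted down (median -0.38, adjusted p = 0.00913, adjusted p = 0.571 with an estimated correlation), and without fetal replicate 1 its adjusted p was 0.125. Of 30 mature myofibre genes, 10 rose and 4 fell (14 and 4 adjusted over the list alone), with rises of Actn3 (2.57 ± 0.14) and Myh1 (2.01 ± 0.12). The myofibre list shifted up (median 0.64, adjusted p = 0.00145, adjusted p = 0.581 with an estimated correlation), with 8.04 on fetal replicate 1, above adolescent replicate 1 (7.97), so the rise rests on fetal replicates 2 and 3 (7.31 and 7.20).

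Of 30 S phase genes, 0 rose and 12 fell (0 and 16 adjusted over the list alone), among them Ccne1 (-2.08 ± 0.26) and Cdc6 (-1.01 ± 0.21). The S phase list shifted down (median -0.74, adjusted p = 1.93e-08, adjusted p = 0.433 with an estimated correlation). Of 34 G2 and M phase genes, 0 rose and 9 fell (0 and 11 adjusted over the list alone), such as Aurka (-1.05 ± 0.18) and Bub1b (-0.90 ± 0.17). Mki67 (-0.40 ± 0.57) did not pass, its SE including the wide adult spread, but fetal (10.8 to 11.0) and adolescent arrays (10.5 to 10.6) did not overlap. The G2 and M list shifted down (median -0.66, adjusted p = 9.13e-07, adjusted p = 0.530 with an estimated correlation). Of 19 cell cycle inhibitor and senescence genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone), with rises of Trp53inp1 (1.33 ± 0.14) and Cdkn1b (0.53 ± 0.10), not called as a list (median 0.21, adjusted p = 0.0548). Cdkn2a, the senescence marker p16, did not pass (0.15 ± 0.12). Of 21 imprinted and fetal growth genes, 0 rose and 14 fell (0 and 19 adjusted over the list alone), including Asb4 (-2.96 ± 0.11), Peg10 (-2.44 ± 0.24) and the growth factor Igf2 (-1.12 ± 0.11). The imprinted list shifted down (median -0.71, adjusted p = 8.01e-13, adjusted p = 0.0707 with an estimated correlation). Of 21 let-7 target and oncofetal genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone), with a fall of Igf2bp1 (-2.84 ± 0.13) and a rise of Ccnd1 (1.59 ± 0.17). The let-7 list shifted down (median -0.12, adjusted p = 0.00940, adjusted p = 0.231 with an estimated correlation).

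Of 42 genes of the JAK-STAT cytokine pathway, 15 rose and 3 fell (16 and 3 adjusted over the list alone), with rises of Bcl6 (2.66 ± 0.10), Cebpd (1.64 ± 0.14) and Stat5a (0.97 ± 0.10) and a fall of Ccnd2 (-1.79 ± 0.14). Socs3 (-0.36 ± 0.18), Stat3 (0.09 ± 0.10) and Jak2 (0.10 ± 0.14) did not pass, and the JAK-STAT list shifted up (median 0.21, adjusted p = 7.16e-04, adjusted p = 0.0707 with an estimated correlation). Of 34 interferon response genes, 21 rose and 0 fell (25 and 0 adjusted over the list alone), among them Ifih1 (1.69 ± 0.16) and Parp14 (1.90 ± 0.20). The interferon list shifted up (median 0.67, adjusted p = 7.28e-10, adjusted p = 0.242 with an estimated correlation). Of 16 antigen presentation genes, 11 rose and 0 fell (14 and 0 adjusted over the list alone), including H2-Q4 (2.41 ± 0.18) and the peptide transporters Tap1 (1.02 ± 0.10) and Tap2 (1.41 ± 0.11). The presentation list shifted up (median 1.06, adjusted p = 1.04e-09, adjusted p = 0.159 with an estimated correlation). Of 25 Notch pathway genes, 11 rose and 1 fell (14 and 2 adjusted over the list alone), with rises of Dll4 (1.19 ± 0.13) and Hey1 (0.94 ± 0.10) and a fall of Lfng (-2.69 ± 0.14). The Notch list shifted up (median 0.32, adjusted p = 2.53e-04, adjusted p = 0.159 with an estimated correlation). Of 38 Wnt pathway genes, 2 rose and 12 fell (2 and 13 adjusted over the list alone), among them Fzd2 (-1.62 ± 0.12) and Sfrp2 (-1.91 ± 0.20). The Wnt list shifted down (median -0.17, adjusted p = 7.16e-04, adjusted p = 0.195 with an estimated correlation). Of 40 TGF-beta and BMP genes, 15 rose and 4 fell (15 and 6 adjusted over the list alone), with a fall of Bmp7 (-2.39 ± 0.11) and rises of Id3 (1.15 ± 0.11) and Tgfbr3 (1.29 ± 0.13), not called as a list (median -0.02, mean 0.00, test up, adjusted p = 0.411).

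Of 31 collagen genes, 2 rose and 8 fell (2 and 8 adjusted over the list alone), among them Col18a1 (-1.40 ± 0.13) and Col1a2 (-1.11 ± 0.13). The collagen list shifted down (median -0.11, adjusted p = 0.00466, adjusted p = 0.358 with an estimated correlation). Of 39 laminin, fibronectin and other matrix genes, 7 rose and 13 fell (8 and 15 adjusted over the list alone), with a fall of Lamb1 (-2.04 ± 0.13) and a rise of Prelp (3.06 ± 0.14). The matrix list shifted down (median -0.22, adjusted p = 0.00466, adjusted p = 0.315 with an estimated correlation), and without fetal replicate 1 its adjusted p was 0.0783. Of 23 glycolysis genes, 2 rose and 10 fell (5 and 10 adjusted over the list alone), such as Tpi1 (-1.02 ± 0.11) and Pfkl (-1.30 ± 0.10). The glycolysis list shifted down (median -0.20, adjusted p = 0.0221, adjusted p = 0.195 with an estimated correlation). Of 29 fatty acid and lipid genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), including Lpl (1.95 ± 0.11) and Cpt1a (1.83 ± 0.12). The lipid list shifted up (median 0.21, adjusted p = 0.00466, adjusted p = 0.444 with an estimated correlation). Of 31 antioxidant genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone), with rises of Gstm1 (1.91 ± 0.09) and Sod3 (1.68 ± 0.13). The antioxidant list shifted up (median 0.22, adjusted p = 1.41e-04, adjusted p = 0.397 with an estimated correlation). Of 33 immediate early and dissociation stress genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone), among them Hspa1a (2.89 ± 0.28) and Dusp1 (1.29 ± 0.11). The stress list shifted up (median 0.29, adjusted p = 0.00161, adjusted p = 0.397 with an estimated correlation). Of 42 oxidative phosphorylation genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), the rise being that of Cox7a1 (1.67 ± 0.28), not called as a list (median -0.01, mean 0.02, test down, adjusted p = 0.690). Of 40 Hox and limb position genes, 9 rose and 8 fell (9 and 10 adjusted over the list alone), with a rise of the hindlimb factor Tbx4 (0.78 ± 0.10) and a fall of Hoxa13 (-0.77 ± 0.11), not called as a list (median -0.05, adjusted p = 0.604). Fetal cells came from forelimb and hindlimb and adolescent cells from hindlimb alone. Of 33 polycomb and chromatin genes, 4 rose and 6 fell (8 and 7 adjusted over the list alone), not called as a list (median -0.12, adjusted p = 0.346).

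Markers of other cells also moved between these stages. Of 21 endothelial genes, 18 rose and 0 fell (20 and 0 adjusted over the list alone), including Ptprb (2.68 ± 0.32) and Flt1 (2.13 ± 0.26). The endothelial list shifted up (median 1.21, adjusted p = 1.03e-12, adjusted p = 0.263 with an estimated correlation), in the same direction as Dll4 and the Notch, interferon and lipid lists. Of 16 smooth muscle and pericyte genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone), with a rise of Steap4 (1.31 ± 0.17) and a fall of Cspg4 (-1.55 ± 0.12). The pericyte list, which also holds Rgs5 and Des, shifted up (median 0.73, adjusted p = 5.90e-04, adjusted p = 0.195 with an estimated correlation). Of 12 Schwann and glial genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a rise of Mbp (1.22 ± 0.09) and a fall of Erbb3 (-1.28 ± 0.09). The glial list shifted up (median 0.18, adjusted p = 0.0234, adjusted p = 0.318 with an estimated correlation). Of 21 fibroblast genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone), not called as a list (median -0.18, adjusted p = 0.493). Of 22 macrophage genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), not called as a list (median 0.07, adjusted p = 0.459). Of 12 housekeeping genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), the rise being that of B2m, not called as a list (median -0.04, mean 0.05, test down, adjusted p = 0.832). No gene passed, over all genes or adjusted over the list alone, among 16 lymphocyte (median 0.08, adjusted p = 0.546), 13 neutrophil (median 0.01, mean -0.03, test down, adjusted p = 0.661) and 10 erythroid genes (median -0.01, adjusted p = 0.546). Of the 33 lists 22 were called, 13 higher and 9 lower, and 0 with an estimated correlation, where over all alternatives their adjusted p lay between 5.76e-17 and 0.581.

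The comparison of adult with adolescent cells addressed the change from growing to mature muscle. Genes of cell division were lower in adult cells. Top2a, the topoisomerase of replicating chromosomes, was 12.4-fold lower (log2 difference -3.63 ± 0.50), and Bub1 (-3.57 ± 0.54), Cdk1 (-3.24 ± 0.44), the mitotic kinase, Kif11 (-3.35 ± 0.54) and Mki67 (-3.11 ± 0.57) fell as well. Falls of similar size were found for Esco2 (-3.50 ± 0.54), Ect2 (-3.28 ± 0.48), Anln (-3.23 ± 0.55), Knl1 (-3.18 ± 0.41) and Nrk (-3.11 ± 0.12, a lower bound with an adult 4.66 near the receptor signal). Without adult replicate 1 the difference was -4.44 for Top2a, -4.38 for Bub1, -4.03 for Mki67, -3.87 for Cdk1, -4.20 for Kif11, -4.37 for Esco2, -4.01 for Ect2, -4.08 for Anln and -3.80 for Knl1. Akr1c14, a hydroxysteroid dehydrogenase, was 10.5-fold higher in adult cells (3.40 ± 0.20). Greb1 (2.69 ± 0.26), an oestrogen-responsive gene, Slco2a1 (2.57 ± 0.30), Tshr (2.39 ± 0.17), the thyrotropin receptor, and Car12 (2.38 ± 0.11) rose too. So did Dbx1 (2.51 ± 0.14), P2ry14 (2.42 ± 0.14), Lncpint (2.31 ± 0.19), Gabre (2.25 ± 0.13) and Gpnmb (2.11 ± 0.16).

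In all, 3941 genes passed (909 higher and 3032 lower in adult cells), and 631 of them differed at least 2-fold (89 higher and 542 lower). With each array centred on its median the split was 517 higher and 4084 lower. The groups did not overlap for 7169 genes (36.0%), where chance gives 10%. The count was 10757 (5061 higher and 5696 lower, 1182 at least 2-fold) without adult replicate 1, 2464, 2385 and 2249 without adolescent replicates 1, 2 and 3, and 1876 and 1938 without adult replicates 2 and 3. It was 323 with replicates 2 and 3 of each stage averaged.

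Of 34 G2 and M phase genes, 0 rose and 34 fell (0 and 34 adjusted over the list alone), with examples in Bub1b (-2.32 ± 0.17), Melk (-2.56 ± 0.24) and Kif2c (-2.36 ± 0.22). The G2 and M list shifted down (median -2.59, adjusted p = 6.62e-25, adjusted p = 0.242 with an estimated correlation). Of 30 S phase genes, 0 rose and 29 fell (0 and 30 adjusted over the list alone), including Ccne1 (-1.97 ± 0.26) and Chaf1a (-1.26 ± 0.15). The S phase list shifted down (median -1.65, adjusted p = 2.57e-17, adjusted p = 0.275 with an estimated correlation). Of 19 cell cycle inhibitor and senescence genes, 2 rose and 8 fell (2 and 9 adjusted over the list alone), among them Lmnb1 (-2.10 ± 0.20), a nuclear lamin, Rb1 (-1.01 ± 0.21) and, upward, Btg2 (0.92 ± 0.14). The inhibitor list shifted down (median -0.20, adjusted p = 0.0335, adjusted p = 0.472 with an estimated correlation), and without adult replicate 3 its adjusted p was 0.0661. Cdkn2a did not pass (0.10 ± 0.12). Of 21 imprinted and fetal growth genes, 0 rose and 14 fell (2 and 14 adjusted over the list alone), with Dlk1 (-2.24 ± 0.21) and Igf2 (-0.92 ± 0.11) lower. The imprinted list shifted down (median -0.60, adjusted p = 1.88e-05, adjusted p = 0.195 with an estimated correlation). Of 21 let-7 target and oncofetal genes, 0 rose and 4 fell (1 and 4 adjusted over the list alone), not called as a list (median 0.13, mean -0.07, test up, adjusted p = 0.740).

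Of 25 satellite cell identity genes, 4 rose and 3 fell (6 and 6 adjusted over the list alone), with rises of Pax7 (0.64 ± 0.10) and Sdc4 (0.68 ± 0.13) and a fall of Msc (-0.71 ± 0.16), not called as a list (median 0.05, mean -0.03, test up, adjusted p = 0.591). Myf5 rose (0.44 ± 0.12), a call lost without adolescent replicate 2 (adjusted p = 0.0686) or 3 (adjusted p = 0.0928), and over its alternatives the adjusted p ran from 1.13e-04 to 1.00. Spry1 rose (0.44 ± 0.09), Myog fell (-2.00 ± 0.44, and -2.69 without adult replicate 1), and Pax3 (0.26 ± 0.11), Myod1 (-0.10 ± 0.11) and Calcr (0.08 ± 0.09) did not pass. Of 29 quiescence genes, 12 rose and 5 fell (14 and 6 adjusted over the list alone), among them Bmp6 (0.95 ± 0.14) and Dio2 (0.98 ± 0.13). The quiescence list shifted up (median 0.29, adjusted p = 0.00940, adjusted p = 0.263 with an estimated correlation), and without adult replicate 1 its adjusted p was 0.187. Of 30 muscle commitment genes, 1 rose and 13 fell (1 and 17 adjusted over the list alone), including Mymk (-1.71 ± 0.29), the fusion protein myomaker, Actc1 (-2.03 ± 0.35) and Chrna1 (-0.93 ± 0.18). The commitment list shifted down (median -0.73, adjusted p = 6.64e-05, adjusted p = 0.397 with an estimated correlation). Of 30 mature myofibre genes, 0 rose and 15 fell (0 and 21 adjusted over the list alone), such as Tpm1 (-1.38 ± 0.14) and Myh4 (-1.21 ± 0.18). The myofibre list shifted down (median -0.84, adjusted p = 2.76e-07, adjusted p = 0.397 with an estimated correlation).

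Of 33 immediate early and dissociation stress genes, 19 rose and 1 fell (21 and 1 adjusted over the list alone), among them Nr4a1 (1.75 ± 0.25) and Jund (1.26 ± 0.17). The stress list shifted up (median 0.55, adjusted p = 5.57e-09, adjusted p = 0.195 with an estimated correlation). Of 42 oxidative phosphorylation genes, 0 rose and 23 fell (0 and 28 adjusted over the list alone), including Sdhd (-1.03 ± 0.15) and Atp5a1 (-0.64 ± 0.09). The respiration list shifted down (median -0.55, adjusted p = 3.81e-10, adjusted p = 0.397 with an estimated correlation), with a level of 9.59 on adult replicate 1, 8.88 on adult replicates 2 and 3, and 9.63 to 9.79 on adolescent arrays. Of 29 fatty acid and lipid genes, 2 rose and 14 fell (3 and 18 adjusted over the list alone), with falls of Acadl (-0.82 ± 0.14) and Etfa (-0.67 ± 0.12). The lipid list shifted down (median -0.40, adjusted p = 8.90e-04, adjusted p = 0.397 with an estimated correlation), with 8.39 on adult replicate 1 and 8.14 and 8.13 on adult replicates 2 and 3. Of 39 laminin, fibronectin and other matrix genes, 6 rose and 17 fell (6 and 20 adjusted over the list alone), with a fall of Lamb1 (-1.30 ± 0.13) and a rise of Ogn (1.24 ± 0.15). The matrix list shifted down (median -0.29, adjusted p = 0.00726, adjusted p = 0.336 with an estimated correlation), and without adult replicate 1 its adjusted p was 0.0970. Of 31 collagen genes, 1 rose and 8 fell (2 and 8 adjusted over the list alone), not called as a list (median 0.06, mean -0.14, test down, adjusted p = 0.459). Of 23 glycolysis genes, 1 rose and 7 fell (1 and 9 adjusted over the list alone), not called as a list (median -0.26, adjusted p = 0.0548). Of 31 antioxidant genes, 5 rose and 11 fell (5 and 12 adjusted over the list alone), not called as a list (median -0.20, adjusted p = 0.248).

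Of 42 JAK-STAT genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), with rises of Cebpd (1.90 ± 0.14), Cebpb (1.07 ± 0.16) and Socs3, a feedback inhibitor of cytokine signalling (1.03 ± 0.18), not called as a list (median 0.03, adjusted p = 0.207). Stat3 (-0.05 ± 0.10) and Jak2 (-0.20 ± 0.14) did not pass. Of 25 Notch pathway genes, 3 rose and 10 fell (5 and 11 adjusted over the list alone), with a rise of Hes1 (0.99 ± 0.10) and falls of Nrarp (-1.16 ± 0.11) and Dll4 (-0.79 ± 0.13), not called as a list (median -0.26, adjusted p = 0.167). Of 40 TGF-beta and BMP genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone), with rises of Id3 (1.19 ± 0.11) and Id1 (1.08 ± 0.14), not called as a list (median -0.06, mean 0.06, test up, adjusted p = 0.334). Of 38 Wnt pathway genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone), not called as a list (median 0.02, mean -0.05, test down, adjusted p = 0.832). Of 34 interferon response genes, 1 rose and 2 fell (1 and 1 adjusted over the list alone), not called as a list (median 0.02, mean -0.03, test up, adjusted p = 0.690). Of 16 antigen presentation genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone), not called as a list (median 0.30, adjusted p = 0.0630), but called with replicate number as a block (adjusted p = 0.0402). Of 40 Hox and limb position genes, 3 rose and 2 fell (1 and 2 adjusted over the list alone), not called as a list (median 0.09, adjusted p = 0.0951). Of 33 polycomb and chromatin genes, 3 rose and 6 fell (4 and 10 adjusted over the list alone), not called as a list (median -0.13, adjusted p = 0.332).

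Of 21 endothelial genes, 0 rose and 9 fell (0 and 15 adjusted over the list alone), including Esam (-1.08 ± 0.20) and Mmrn2 (-1.03 ± 0.22). The endothelial list shifted down (median -0.54, adjusted p = 3.53e-05, adjusted p = 0.472 with an estimated correlation), in the direction in which Dll4 and Nrarp moved. Of 21 fibroblast genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone), with falls of Col1a1 (-0.99 ± 0.17) and Scara5 (-0.61 ± 0.13). The fibroblast list shifted down (median -0.29, adjusted p = 0.0418, adjusted p = 0.589 with an estimated correlation), a call lost without adolescent replicate 2 (adjusted p = 0.0831), adolescent replicate 3 (adjusted p = 0.0654) or adult replicate 1 (adjusted p = 0.271). Of 13 neutrophil genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone). The neutrophil list shifted up (median 0.20, adjusted p = 0.0122, adjusted p = 0.337 with an estimated correlation). Of 16 lymphocyte genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). The lymphocyte list shifted up (median 0.26, adjusted p = 0.00726, adjusted p = 0.555 with an estimated correlation). Both of these lists lay near 5 on the log2 scale in adolescent cells (4.90 ± 0.06 and 4.92 ± 0.09, SD, n = 3), and the receptor genes were higher on 2 of the 3 adult arrays. Of 12 Schwann and glial genes, 1 rose and 4 fell (2 and 5 adjusted over the list alone), not called as a list (median -0.21, adjusted p = 0.178). Of 16 smooth muscle and pericyte genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone), not called as a list (median -0.11, adjusted p = 0.586). No gene passed, over all genes or adjusted over the list alone, among 22 macrophage (median 0.07, mean -0.01, test up, adjusted p = 0.789) and 10 erythroid genes (median 0.18, adjusted p = 0.134). Of 12 housekeeping genes, 0 rose and 5 fell (0 and 9 adjusted over the list alone), including Tubb5 (-1.15 ± 0.16) and Polr2a (-0.57 ± 0.11). The housekeeping list shifted down (median -0.44, adjusted p = 0.00161, adjusted p = 0.398 with an estimated correlation), with 10.5 on adult replicate 1, 9.99 on adult replicates 2 and 3 and 10.6 on adolescent arrays. Of the 33 lists 16 were called, 4 higher and 12 lower. The split was 7 and 8 with dim genes left out by group mean, 7 and 5 by overall mean, and 0 lists were called with an estimated correlation, where over all alternatives their adjusted p lay between 8.37e-39 and 0.900.

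**Figure D3:**
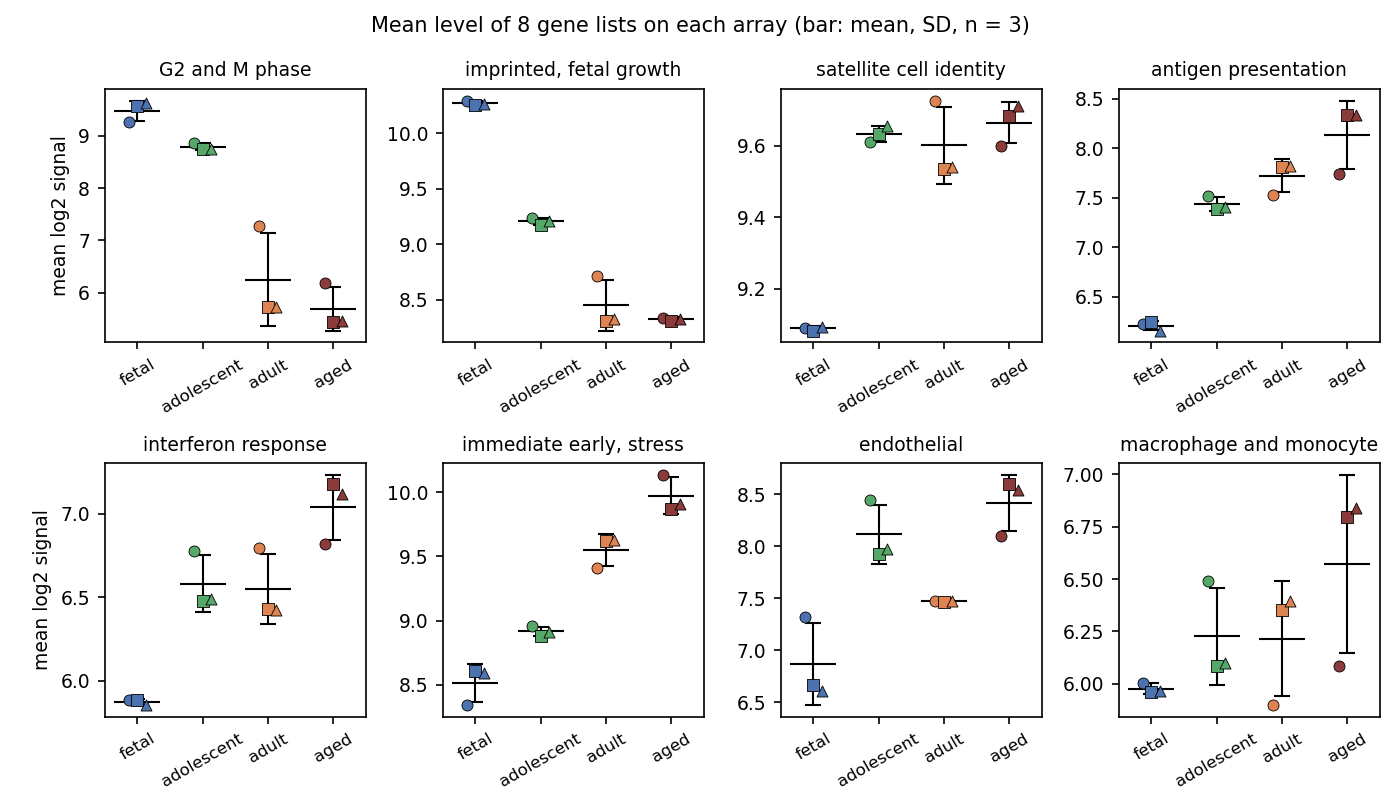
Mean log2 signal of 8 gene lists on each array by stage, with bars for the mean and SD (n = 3). The G2 and M phase list falls from 9.48 in fetal to 5.69 in aged cells, and the endothelial list is higher in aged than in adult cells.

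The comparison of aged with adult cells addressed what differs in satellite cells after 1 year of age. Grin2a, a subunit of the NMDA glutamate receptor, was 4.34-fold higher in aged cells (log2 difference 2.12 ± 0.22). Doc2b, a calcium sensor of vesicle release, was 3.27-fold higher (1.71 ± 0.12), and Gabra3 (1.73 ± 0.17), a GABA receptor subunit, Slc24a2 (1.74 ± 0.16), Anks1b (1.86 ± 0.16), Spock3 (1.89 ± 0.23) and Slfn5 (1.74 ± 0.24) rose too. Rassf9 (1.89 ± 0.28) and Calhm5 (1.79 ± 0.19) completed the large rises that passed without each single adult or aged array. Jchain, the joining chain of secreted antibodies, rose by 3.15 ± 0.75, a lower bound with an adult mean of 4.00 near the receptor signal, with 8.50 and 8.42 on aged replicates 2 and 3 and 4.54 on aged replicate 1. Its difference was 4.46, 2.48 and 2.52 without aged replicates 1, 2 and 3. Its call was lost without adult replicate 2 (adjusted p = 0.127), adult replicate 3 (adjusted p = 0.119), aged replicate 2 (adjusted p = 0.190) or aged replicate 3 (adjusted p = 0.178), with a range of 8.05e-10 to 0.818 over its alternatives.

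Falls were smaller, with Ret (-0.75 ± 0.13) the one among the 10 largest that passed without each single adult or aged array. Actc1, cardiac actin, fell by 1.65, a call lost without aged replicate 2 (adjusted p = 0.118) or 3 (adjusted p = 0.117), with a range of 2.00e-08 to 1.00 over its alternatives. Calls also lost without an array, given with the array whose removal raised p most, were Alpl (-0.85 ± 0.18, adjusted p = 0.109 without aged replicate 2), Col26a1 (-0.78 ± 0.18, adjusted p = 0.182 without aged replicate 2), Ccnd1 (-0.74 ± 0.17, adjusted p = 0.166 without aged replicate 2) and Tac4 (-0.74 ± 0.18, adjusted p = 0.171 without adult replicate 3). The same held for Micall2, Trmt112, Fhl3 and Tubb4a. Of the 74 named genes that passed here, 41 lost their call without at least 1 adult or aged array. The other 33 passed without each of these arrays, and 0 changed sign. Over all alternatives the adjusted p of these 74 genes lay between 1.96e-11 and 1.00.

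In all, 697 genes passed (654 higher and 43 lower in aged cells), 155 of them at least 2-fold (154 higher and 1 lower), and 4217 had an unadjusted p under 0.05. The groups did not overlap for 3196 genes (16.0%), where chance gives 10%. The count was 7844 (4042 higher and 3802 lower, 306 at least 2-fold) without adult replicate 1 and 2214 (277) without aged replicate 1, but 269 (105), 289 (112), 214 (80) and 216 (90) without adult replicates 2 and 3 and aged replicates 2 and 3. It was 2 with replicates 2 and 3 of each stage averaged.

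Of 25 satellite cell identity genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), not called as a list (median 0.03, adjusted p = 0.700). Pax7 (0.03 ± 0.10), Pax3 (0.07 ± 0.11), Myf5 (0.21 ± 0.12), Myod1 (-0.21 ± 0.11), Myog (-1.17 ± 0.44), Spry1 (0.07 ± 0.09) and Calcr (0.06 ± 0.09) did not pass. Of 29 quiescence genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone), with Angpt1 (1.56 ± 0.18) and Klf4 (0.90 ± 0.11) among them. The quiescence list shifted up (median 0.12, adjusted p = 0.00910, adjusted p = 0.263 with an estimated correlation), with 9.70 on adult and aged replicate 1 alike. It holds the vessel genes Tek and Rgs5, and the endothelial and stress lists rose too. Of 30 muscle commitment genes, 1 rose and 1 fell (3 and 4 adjusted over the list alone), the rise being that of Jam2 (1.39 ± 0.16), not called as a list (median -0.13, adjusted p = 0.167). No gene passed, over all genes or adjusted over the list alone, among 30 mature myofibre (median 0.01, mean 0.01, test down, adjusted p = 0.832), 30 S phase (median -0.16, adjusted p = 0.194) and 42 oxidative phosphorylation genes (median 0.02, mean 0.03, test down, adjusted p = 0.995). Without adult replicate 1 the tests of the S phase and oxidative phosphorylation lists reversed (medians 0.29 and 0.23). Of 34 G2 and M phase genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), Mki67 (-0.77 ± 0.57) included. The G2 and M list still shifted down (median -0.58, adjusted p = 4.85e-06, adjusted p = 0.566 with an estimated correlation), and without adult replicate 1 its median was 0.00 (adjusted p = 0.650). Of 19 cell cycle inhibitor and senescence genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), not called as a list (median 0.19, adjusted p = 0.0962). Cdkn2a did not pass (-0.20 ± 0.12).

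Of 42 JAK-STAT genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone), with rises of Pim1 (0.94 ± 0.13) and Socs3 (0.82 ± 0.18). The JAK-STAT list shifted up (median 0.18, adjusted p = 5.44e-05, adjusted p = 0.0549 with an estimated correlation). The call of Socs3 was lost without adult replicate 2 (adjusted p = 0.0678), adult replicate 3 (adjusted p = 0.0878) or aged replicate 3 (adjusted p = 0.0973), with 1.07e-06 to 1.00 over its alternatives. Stat3 (0.23 ± 0.10) and Jak2 (0.51 ± 0.14, adjusted p = 0.0670) did not pass. Of 34 interferon response genes, 6 rose and 0 fell (16 and 0 adjusted over the list alone), with a rise of Irf1 (1.10 ± 0.20, adjusted p = 0.0599 without aged replicate 2) in the fit of all arrays. The interferon list shifted up (median 0.49, adjusted p = 2.27e-09, adjusted p = 0.258 with an estimated correlation), with 6.82 on aged replicate 1 and 6.79 on adult replicate 1 against 7.18 and 7.12 on aged replicates 2 and 3. Of 16 antigen presentation genes, 1 rose and 0 fell (2 and 0 adjusted over the list alone), the rise being that of H2-Q4 (1.14 ± 0.18). The presentation list shifted up (median 0.46, adjusted p = 6.63e-04, adjusted p = 0.318 with an estimated correlation), and without adult replicate 1 its adjusted p was 0.0664. Aged replicate 1 (7.74) lay below adult replicates 2 and 3 (7.82), and the rise was on aged replicates 2 and 3 (8.34 and 8.33), where the endothelial (8.60 and 8.55) and macrophage lists (6.80 and 6.84) were highest.

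Of 21 endothelial genes, 13 rose and 0 fell (20 and 0 adjusted over the list alone), including Kdr (1.47 ± 0.25), a receptor for vascular endothelial growth factor, Esam (1.23 ± 0.20) and Tie1 (1.07 ± 0.17). The endothelial list shifted up (median 0.92, adjusted p = 1.18e-14, adjusted p = 0.242 with an estimated correlation), from 7.47 ± 0.01 in adult to 8.42 ± 0.27 in aged cells (SD, n = 3). Of 25 Notch pathway genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Dll4 (1.14 ± 0.13), a ligand made by endothelium among other cells, and Nrarp (0.64 ± 0.11). The Notch list shifted up (median 0.22, adjusted p = 1.02e-04, adjusted p = 0.159 with an estimated correlation), in the same direction as the endothelial markers. Of 40 TGF-beta and BMP genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone), such as Id3 (0.84 ± 0.11) and Smad7 (0.77 ± 0.10). The TGF-beta list shifted up (median 0.20, adjusted p = 2.84e-05, adjusted p = 0.195 with an estimated correlation), again with the endothelial markers. Of 29 fatty acid and lipid genes, 3 rose and 0 fell (4 and 1 adjusted over the list alone), with Fabp4 (1.34 ± 0.17) and Cd36 (1.57 ± 0.26), lipid carriers that capillary endothelium also makes. The lipid list shifted up (median 0.18, adjusted p = 0.00360, adjusted p = 0.424 with an estimated correlation), with adult replicate 1 (8.39) at the level of aged replicate 1 (8.38). Of 39 laminin, fibronectin and other matrix genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with Lama4 (1.00 ± 0.17), a laminin chain of vessel walls, Fbln2 (0.86 ± 0.14) and Spock1 (0.97 ± 0.12). The matrix list shifted up (median 0.12, adjusted p = 0.0344, adjusted p = 0.419 with an estimated correlation), and its adjusted p was 0.257 without adult replicate 1 and 0.0604 without aged replicate 3, and its test reversed with the filter on the overall mean. Of 16 smooth muscle and pericyte genes, 3 rose and 0 fell (6 and 1 adjusted over the list alone). The pericyte list shifted up (median 0.22, adjusted p = 0.00283, adjusted p = 0.242 with an estimated correlation).

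Of 33 immediate early and dissociation stress genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone), including Ier3 (1.09 ± 0.14) and Klf2 (0.84 ± 0.10). The stress list shifted up (median 0.33, adjusted p = 1.04e-08, adjusted p = 0.195 with an estimated correlation). Of 23 glycolysis genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone). The glycolysis list shifted up (median 0.07, adjusted p = 0.0250, adjusted p = 0.195 with an estimated correlation), with an adjusted p of 0.0529 without adult replicate 1 and 0.110 without aged replicate 1. Of 31 antioxidant genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone). The antioxidant list shifted up (median 0.11, adjusted p = 0.0214, adjusted p = 0.581 with an estimated correlation), with an adjusted p of 0.119, 0.128 and 0.151 without adult replicate 2, adult replicate 3 and aged replicate 1, and it reversed with the filter on the overall mean. Of 31 collagen genes, 1 rose and 1 fell (3 and 4 adjusted over the list alone). The collagen list shifted down (median -0.20, adjusted p = 0.0143, adjusted p = 0.398 with an estimated correlation), with an adjusted p of 0.0866 without aged replicate 1. Of 33 polycomb and chromatin genes, 0 rose and 0 fell (4 and 1 adjusted over the list alone). The polycomb list shifted up (median 0.13, adjusted p = 0.0466, adjusted p = 0.566 with an estimated correlation), with an adjusted p of 0.182, 0.213, 0.0954 and 0.0921 without adult replicates 2 and 3 and aged replicates 2 and 3. Of 21 imprinted and fetal growth genes, 2 rose and 0 fell (2 and 1 adjusted over the list alone), with Igf2 (0.57 ± 0.11) rising in the fit of all arrays, not called as a list (median -0.07, adjusted p = 0.188). Without adult replicate 2, adult replicate 3 or aged replicate 3 the adjusted p of Igf2 was 0.0710, 0.0702 and 0.0791, with 1.35e-08 to 1.00 over its alternatives. Of 21 let-7 target and oncofetal genes, 1 rose and 1 fell (4 and 1 adjusted over the list alone), not called as a list (median 0.04, adjusted p = 0.870). Of 40 Hox and limb position genes, 1 rose and 0 fell (3 and 1 adjusted over the list alone), not called as a list (median 0.06, adjusted p = 0.186).

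No gene passed, over all genes or adjusted over the list alone, among 22 macrophage genes. The macrophage list shifted up (median 0.31, adjusted p = 0.00409, adjusted p = 0.581 with an estimated correlation), with an adjusted p of 0.453 without adult replicate 1 and 0.0768 without aged replicate 3. Of 21 fibroblast genes, 1 rose and 0 fell (1 and 2 adjusted over the list alone), the rise being that of Mkx (1.14 ± 0.13), a tendon factor, not called as a list (median 0.02, adjusted p = 0.522). Of 12 Schwann and glial genes, 3 rose and 0 fell (3 and 1 adjusted over the list alone), with a rise of Mpzl2 (1.52 ± 0.21), not called as a list (median 0.05, adjusted p = 0.271). The Wnt list (median 0.03, adjusted p = 0.608) and the lymphocyte (median -0.08, mean 0.04, test down, adjusted p = 0.852), neutrophil (median -0.07, adjusted p = 0.588) and erythroid lists (median -0.12, adjusted p = 0.132) had 0 genes that passed, over all genes or adjusted over the list alone. Of 12 housekeeping genes, 0 rose and 0 fell (1 and 0 adjusted over the list alone), not called as a list (median 0.15, adjusted p = 0.135). Of the 33 lists 17 were called, 15 higher and 2 lower. The split was 8 and 5 with dim genes left out by group mean, 5 and 6 by overall mean, and 0 lists were called with an estimated correlation, where over all alternatives their adjusted p lay between 2.75e-43 and 0.956.

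**Figure D4:**
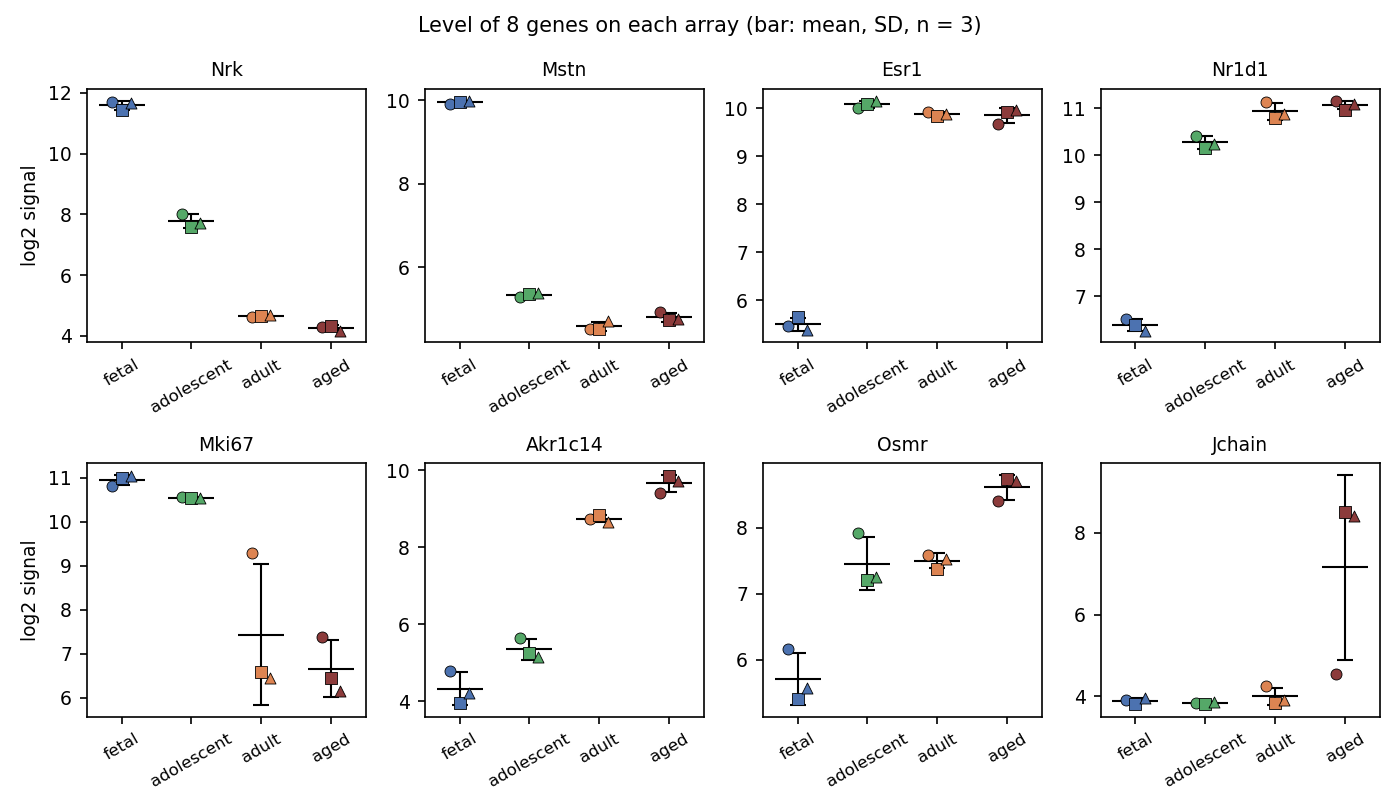
Log2 signal of 8 genes on each array by stage, with bars for the mean and SD (n = 3). Nrk falls from 11.6 in fetal to 4.66 in adult cells, and Jchain is raised on aged replicates 2 and 3 but not on aged replicate 1.

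The comparison of adult with fetal cells spans the whole of prenatal and postnatal growth. Nrk, a kinase of the germinal centre family, fell from 11.6 to 4.66 (log2 difference -6.94 ± 0.12) and Mstn from 9.95 to 4.59 (-5.36 ± 0.09). Adult values near the receptor signal, as for these genes and Cpa3, make the differences lower bounds. Vcan (-5.48 ± 0.17), Tnc (-5.12 ± 0.31) and Fbn2 (-4.68 ± 0.13), matrix genes, Gpc3 (-5.08 ± 0.14), a cell surface proteoglycan, Cpa3 (-5.28 ± 0.21), Bub1 (-4.41 ± 0.54, and -5.22 without adult replicate 1), Nnat (-4.30 ± 0.13) and AW551984 (-4.66 ± 0.26) fell too. Retnla, a secreted resistin-like protein, rose from 3.60, also at the receptor signal, to 8.91 (5.31 ± 0.38). Nr1d1 (4.54 ± 0.12), Esr1 (4.38 ± 0.11), Akr1c14 (4.42 ± 0.20), Hsd11b1 (4.37 ± 0.26), Lama3 (4.41 ± 0.27) and Hspa1a (4.27 ± 0.28), an inducible heat shock protein, rose.

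In all, 8465 genes passed (3806 higher and 4659 lower in adult cells), 2067 of them at least 2-fold (714 higher and 1353 lower). With each array centred on its median the split was 2542 higher and 5201 lower. The groups did not overlap for 9554 genes (47.9%), where chance gives 10%. The count was 12968 (7000 higher and 5968 lower) without adult replicate 1 and 3532 with replicates 2 and 3 of each stage averaged.

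Of 34 G2 and M phase genes, 0 rose and 34 fell (0 and 34 adjusted over the list alone), with Bub1b (-3.23 ± 0.17), Aurka (-2.64 ± 0.18) and Mki67 (-3.51 ± 0.57, and -4.44 without adult replicate 1) among them. The G2 and M list shifted down (median -3.25, adjusted p = 1.03e-19, adjusted p = 0.275 with an estimated correlation). Of 30 S phase genes, 0 rose and 30 fell (0 and 30 adjusted over the list alone), led by Ccne1 (-4.04 ± 0.26). The S phase list shifted down (median -2.48, adjusted p = 1.77e-16, adjusted p = 0.292 with an estimated correlation). Of 19 cell cycle inhibitor and senescence genes, 5 rose and 7 fell (5 and 7 adjusted over the list alone), not called as a list (median -0.08, adjusted p = 0.841). Cdkn2a did not pass (0.25 ± 0.12). Of 25 satellite cell identity genes, 14 rose and 4 fell (15 and 4 adjusted over the list alone), including Pax7 (1.14 ± 0.10), Sdc4 (2.87 ± 0.13) and Fgfr1 (1.22 ± 0.10). The identity list shifted up (median 0.44, adjusted p = 0.00385, adjusted p = 0.315 with an estimated correlation). Pax3 (0.44 ± 0.11), Myf5 (1.21 ± 0.12), Myod1 (0.69 ± 0.11) and Spry1 (1.26 ± 0.09) rose. Myog fell (-1.26 ± 0.44) on adult replicates 2 and 3 (7.32 and 7.49), while adult replicate 1 (9.50) lay above the fetal arrays (9.34 to 9.38). The difference was -1.95 without adult replicate 1. The call was lost without any 1 of adult replicates 2 and 3 (adjusted p = 0.165 and 0.153) and fetal replicates 1, 2 and 3 (adjusted p = 0.0867, 0.0764 and 0.0903), and it ran from 5.80e-08 to 0.736 over its alternatives. Of 29 quiescence genes, 21 rose and 5 fell (21 and 5 adjusted over the list alone), with Calcr (1.93 ± 0.09) and Btg2 (2.08 ± 0.14). The quiescence list shifted up (median 0.97, adjusted p = 2.36e-07, adjusted p = 0.0707 with an estimated correlation). Of 30 muscle commitment genes, 3 rose and 22 fell (3 and 22 adjusted over the list alone), such as Myh3 (-3.90 ± 0.24) and Myl4 (-3.09 ± 0.23). The commitment list shifted down (median -0.99, adjusted p = 1.28e-05, adjusted p = 0.369 with an estimated correlation). Of 30 mature myofibre genes, 8 rose and 8 fell (9 and 8 adjusted over the list alone), with a rise of Actn3 (2.21 ± 0.14) and a fall of Ttn (-2.61 ± 0.19), not called as a list (median 0.03, mean -0.12, test down, adjusted p = 0.845).

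Of 21 imprinted and fetal growth genes, 0 rose and 16 fell (0 and 17 adjusted over the list alone), with Asb4 (-3.97 ± 0.11) and Igf2 (-2.04 ± 0.11). The imprinted list shifted down (median -1.08, adjusted p = 8.40e-11, adjusted p = 0.0707 with an estimated correlation). Of 21 let-7 target and oncofetal genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone), not called as a list (median -0.29, adjusted p = 0.134). Of 16 antigen presentation genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone), including H2-Q4 (2.15 ± 0.18) and Tapbp (1.41 ± 0.11). The presentation list shifted up (median 1.17, adjusted p = 1.22e-07, adjusted p = 0.195 with an estimated correlation). Of 34 interferon response genes, 22 rose and 2 fell (25 and 2 adjusted over the list alone), with Parp14 (2.15 ± 0.20) and Ifih1 (1.83 ± 0.16). The interferon list shifted up (median 0.67, adjusted p = 4.85e-06, adjusted p = 0.352 with an estimated correlation). Of 42 JAK-STAT genes, 19 rose and 6 fell (20 and 7 adjusted over the list alone), with Cebpd (3.54 ± 0.14), Bcl6 (3.10 ± 0.10) and Socs3 (0.67 ± 0.18) higher and Ccnd2 (-2.53 ± 0.14) lower. The JAK-STAT list shifted up (median 0.23, adjusted p = 0.00409, adjusted p = 0.102 with an estimated correlation), and Stat3 (0.04 ± 0.10) and Jak2 (-0.10 ± 0.14) did not pass. Of 25 Notch pathway genes, 10 rose and 7 fell (10 and 7 adjusted over the list alone), with Hes1 (1.57 ± 0.10) and Heyl (1.76 ± 0.15) higher and Lfng (-3.28 ± 0.14) lower, not called as a list (median 0.16, adjusted p = 0.299). Of 38 Wnt pathway genes, 4 rose and 16 fell (4 and 16 adjusted over the list alone), with falls of Sfrp2 (-3.14 ± 0.20) and Fzd2 (-2.10 ± 0.12). The Wnt list shifted down (median -0.25, adjusted p = 0.01, adjusted p = 0.275 with an estimated correlation). Of 40 TGF-beta and BMP genes, 18 rose and 12 fell (18 and 13 adjusted over the list alone), with Id3 (2.34 ± 0.11) higher and Bmp7 (-2.27 ± 0.11) lower, not called as a list (median 0.04, adjusted p = 0.482). Of 40 Hox and limb position genes, 9 rose and 7 fell (9 and 7 adjusted over the list alone), not called as a list (median 0.04, adjusted p = 0.669). Of 33 polycomb and chromatin genes, 7 rose and 13 fell (8 and 13 adjusted over the list alone), not called as a list (median -0.07, adjusted p = 0.203).

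Of 33 immediate early and dissociation stress genes, 25 rose and 3 fell (25 and 3 adjusted over the list alone), with Dusp1 (2.00 ± 0.11) and Junb (2.15 ± 0.16). The stress list shifted up (median 1.01, adjusted p = 2.36e-07, adjusted p = 0.242 with an estimated correlation). Of 42 oxidative phosphorylation genes, 1 rose and 28 fell (1 and 30 adjusted over the list alone), with falls of Ndufb3 (-1.04 ± 0.13) and Sdhd (-1.09 ± 0.15). The respiration list shifted down (median -0.55, adjusted p = 9.13e-07, adjusted p = 0.473 with an estimated correlation), with 8.88 on adult replicates 2 and 3 but 9.59 on adult replicate 1, near fetal arrays (9.63 to 9.71). Of 23 glycolysis genes, 3 rose and 10 fell (3 and 12 adjusted over the list alone). The glycolysis list shifted down (median -0.39, adjusted p = 0.00910, adjusted p = 0.159 with an estimated correlation). Of 29 fatty acid and lipid genes, 7 rose and 13 fell (9 and 13 adjusted over the list alone), not called as a list (median -0.08, mean 0.09, test down, adjusted p = 0.889). Of 31 antioxidant genes, 12 rose and 10 fell (12 and 10 adjusted over the list alone), not called as a list (median -0.09, mean 0.47, test up, adjusted p = 0.344). Of 31 collagen genes, 3 rose and 11 fell (3 and 11 adjusted over the list alone), with falls of Col1a2 (-2.53 ± 0.13) and Col6a3 (-2.11 ± 0.16). The collagen list shifted down (median -0.14, adjusted p = 0.0364, adjusted p = 0.472 with an estimated correlation), with an adjusted p of 0.201 without adult replicate 1. Of 39 laminin, fibronectin and other matrix genes, 10 rose and 21 fell (10 and 21 adjusted over the list alone), with Prelp (4.00 ± 0.14) higher and Lamb1 (-3.34 ± 0.13) lower. The matrix list shifted down (median -0.53, adjusted p = 0.00445, adjusted p = 0.315 with an estimated correlation). Of 12 housekeeping genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone), with Tubb5 (-1.44 ± 0.16) lower. The housekeeping list shifted down (median -0.41, adjusted p = 0.0165, adjusted p = 0.530 with an estimated correlation).

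Of 21 endothelial genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with Ramp2 (1.94 ± 0.16) and Flt1 (1.48 ± 0.26). The endothelial list shifted up (median 0.45, adjusted p = 0.00441, adjusted p = 0.589 with an estimated correlation). Of 16 lymphocyte genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone). The lymphocyte list shifted up (median 0.34, adjusted p = 0.0259, adjusted p = 0.589 with an estimated correlation), with an adjusted p of 0.0679 and 0.0523 without adult replicates 2 and 3, the arrays of raised receptor signal. Of 16 smooth muscle and pericyte genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone), with Rgs5 (2.28 ± 0.22) higher and Cspg4 (-1.82 ± 0.12) lower. The pericyte list shifted up (median 0.61, adjusted p = 0.0419, adjusted p = 0.397 with an estimated correlation), with an adjusted p of 0.155 without adult replicate 1 and 0.0503 without fetal replicate 2. Of 22 macrophage genes, 4 rose and 2 fell (3 and 1 adjusted over the list alone), not called as a list (median 0.05, adjusted p = 0.608). Of 21 fibroblast genes, 5 rose and 9 fell (5 and 9 adjusted over the list alone), not called as a list (median -0.33, adjusted p = 0.148). Of 12 Schwann and glial genes, 6 rose and 3 fell (6 and 4 adjusted over the list alone), not called as a list (median 0.28, adjusted p = 0.422). Of 13 neutrophil genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), not called as a list (median 0.23, adjusted p = 0.178). No gene passed, over all genes or adjusted over the list alone, among 10 erythroid genes (median 0.12, adjusted p = 0.604). Of the 33 lists 19 were called, 9 higher and 10 lower. The split was 9 and 5 with dim genes left out by group mean, 12 and 5 by overall mean, and 0 lists were called with an estimated correlation, where over all alternatives their adjusted p lay between 2.79e-27 and 0.657.

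To ask if aged cells resembled fetal ones, fetal minus adolescent differences were set against aged minus adult ones, which share no array. Across 19938 genes, which are not independent replicates, Pearson's r was -0.11 and Spearman's rho -0.01. The r was 0.10 with all probe sets and -0.05, -0.06 and -0.07 without adult replicate 1, adolescent replicate 1 and fetal replicate 2. Of 399 genes called in both, 113 were higher in fetal and aged cells (56.8 for independent lists) and 11 lower in both (4.33). Another 271 were lower in fetal and higher in aged cells (65.9) and 4 the reverse (3.73). Gene variances shared by both tests can raise these counts. Fisher's exact test of sign on these counts gave an odds ratio of 1.15 (p = 1.00).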

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

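Settings with the receptor level as a covariate, with replicates 2 and 3 averaged and with the 3 arrays of raised receptor signal left out were chosen after seeing the data. Where a value moved, the cause was not tested, except where fewer arrays or a higher bar entered by construction.

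With array weights, whose estimation stopped short of its tolerance, 8034 genes passed in adolescent against fetal, 15088 (7725 higher and 7363 lower, 1031 at least 2-fold) in adult against adolescent, 15776 (8069 and 7707, 555) in aged against adult, 15437 (8559 and 6878) in adult against fetal and 18963 for any stage. Against a minimum fold, a higher bar, the counts were 789, 260 (260), 13 (13) and 1853. With replicates 2 and 3 averaged, which leaves 2 values per stage, they were 1472, 323 (261), 2 (2), 3532 and 3430. Leaving out the 3 arrays of raised receptor signal leaves 2 aged arrays and adult replicate 1, which stands apart, as the single adult array, assumed to vary like the other groups, so its adult values compare that array alone. The counts were then 5904 in adolescent against fetal, 1586 (327) in adult against adolescent and 1608 (447) in aged against adult, and 15 called lists lost their calls, lipid, housekeeping, respiration and quiescence among them.

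With the 2 stages compared alone in the fit, 2145 genes passed in adult against adolescent and 176 in aged against adult, with fewer arrays to estimate the spread. For aged against adult, all probe sets gave 445 calls, a floor at the dim level left 87 genes at least 2-fold and the filter on the overall mean 100. By camera with an estimated correlation 0 lists were called. In aged against adult, 11 lists were called with fry (11 higher and 0 lower) and 11 with the filter on the overall mean (5 and 6). The correlation of the fetal and aged differences was -0.145 without dim genes, -0.0109 by Spearman and 0.104 with all probe sets, a reversal. The agreement of replicates was 0.982 and 0.976 with the filters on the group and the overall mean.

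With replicate number as a block, 3494 genes passed in adolescent against fetal, 518 in aged against adult and 7683 in adult against fetal. In adult against adolescent only the antigen presentation list changed its call. Over all stages 6 of 18 pairs with the same number correlated above 0.1 (-0.435 to 0.362), so a pairing is not supported. No slide or scan date is given. With the receptor level as a covariate 709 genes passed in aged against adult.

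Leaving out each array in turn gave 1876 to 10757 genes in adult against adolescent (501 to 1182 at least 2-fold), 214 to 7844 in aged against adult (80 to 306), 5923 to 12968 in adult against fetal and 6665 to 14192 for any stage. The counts of lists stayed within 20 to 23, 14 to 18, 15 to 18 and 17 to 19 in adolescent against fetal, adult against adolescent, aged against adult and adult against fetal. The correlation of the fetal and aged differences ran from -0.144 to -0.0504.

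Reversed tests on lists in aged against adult were those of matrix (median 0.12) and antioxidant genes (0.093) with the filter on the overall mean, and of oxidative phosphorylation with array weights (0.30). Without adult replicate 1 oxidative phosphorylation (0.23, lowest -0.10) and S phase (0.29, lowest -0.29) reversed. With adult replicate 1 as the single adult array, Myog in adult against fetal (0.14), macrophage (-0.26) and lymphocyte genes (-0.061) in adult against adolescent, and antioxidant (-0.11), polycomb (0.0043) and lymphocyte genes (0.24) in aged against adult reversed.

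Of 132 list results 74 were called and 74 lost the call under at least 1 alternative. Of 610 results of named genes 469 were called and 212 lost the call at least once. Alternatives to list results numbered 2296 the same, 222 weaker, 98 stronger, 126 moved and 10 reversed, and those to named genes 10850, 802, 324, 44 and 1. No called list or named gene changed sign under either scaling. Signal over background limits low genes: receptor genes, taken as background, lay at 3.79 to 4.50, and differences between levels under 6 carry that uncertainty.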

Other observations

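All tests below except the splits of the samples were chosen after the result was seen.

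Other splits of the 6 arrays of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. Just 1 split, the real one, reached its number of genes in adolescent against fetal (3739, highest other 0), adult against adolescent (3941, highest other 0) and adult against fetal (8465, highest other 0), and likewise at 2-fold (991, 631 and 2067, highest others 0). Adolescent and adult arrays of the same number deviated together, and the 3 other splits that part all pairs called 0 genes each and 8, 10 and 18 lists. In aged against adult 2 splits gave as many: the split of adult replicate 1 with aged replicates 2 and 3 from the others called 8833 genes against 697, and 209 against 155 at 2-fold. That split follows the raised receptor signal of adult replicates 2 and 3 and aged replicate 1 and points to a structure of the samples. For lists, 1 split gave as many in adolescent against fetal (22, highest other 21), 4 in adult against adolescent (16, highest other 18), 1 in aged against adult (17, highest other 16) and 1 in adult against fetal (19, highest other 15). For any stage, 1 of 100 splits, the real one, reached 8293 genes (highest other 5289), which excludes chance only if the 12 arrays are exchangeable. Replicates 2 and 3 of each stage lay closest to each other, no split that keeps this was run, and 3430 genes passed with them averaged.

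Adult replicate 1 lay apart from adult replicates 2 and 3. A swap with an adolescent array is argued against by the nearest arrays, as 3 of 3 adolescent arrays lay nearest to their own group. A wrong label on an adolescent array is argued against by its median position of 0.545 between adolescent (0) and aged (1), where the highest adolescent array stood at 0.0260. Compressed values of the other adult arrays are argued against as the whole cause by the G2 and M list, 1.46 higher on adult replicate 1 where random sets of genes of like level had an upper bound of 0.388. More cycling cells, or a younger age within 2 to 3 months, may be involved and were not tested.

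More genes were higher than lower in aged against adult cells (654 and 43). With the receptor level as a covariate 84.3% of called genes were higher, but that level splits the adult arrays as the distance of adult replicate 1 does, so a part of background cannot be told apart from that array's difference. Without the 3 raised arrays it was 60.5% with adult replicate 1 as the single adult array, which decides nothing. Without adult replicate 1 it was 51.5% (4042 higher and 3802 lower), but the adult arrays left are the 2 of raised signal, so spread added by this array cannot be told apart from background. A biological bias toward higher expression with age stays open and untested.

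Endothelial markers were higher in aged (Pecam1 8.33, 9.31 and 9.22) than in adult cells (7.78, 7.41 and 7.47). Of other cell lists with an adult mean of at least 6, 4 of 4 rose less by more than 2 SE (smallest gap 0.588). A lower share of satellite cells stays open, as more endothelial cells alone could cause it. More endothelial cells in the sort may contribute. The markers correlated within groups (mean r 0.683, 95th percentile for matched genes 0.277), but so did the G2 and M list (0.827), so this decides nothing. Of the 21 markers 1 is in another list, 20 had an adult mean of at least 6, and sorting on ZsGreen would remove cells without it. Expression by satellite cells themselves stays open.

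Further lists were drawn up once the genes that led to them had been seen, with p adjusted over 28 tests. Of 17 circadian clock genes, 10 rose and 1 fell in adolescent against fetal (median 0.68, adjusted p = 2.46e-06, or 0.00888 with an estimated correlation), such as Bhlhe41 (3.02 ± 0.22) and Nr1d2 (2.05 ± 0.19), and 9 and 1 of 16 without Nr1d1 (adjusted p = 1.92e-05, or 0.00888). In adult against fetal 14 rose and 1 fell (1.03, adjusted p = 5.20e-06, or 0.00888), in adult against adolescent 5 and 0 (0.10, adjusted p = 0.0718) and in aged against adult 1 and 0 (0.20, adjusted p = 0.00345, or 0.0442). The time of day of dissection is not given. Of 13 mast cell genes, 1 rose and 9 fell in adolescent against fetal (-0.56, adjusted p = 4.40e-06, or 0.177), with Hdc (-1.55 ± 0.17) and Tpsb2 (-1.34 ± 0.12), and 1 and 8 without Cpa3 (adjusted p = 4.46e-05, or 0.221). In adult against fetal 0 rose and 8 fell (adjusted p = 9.11e-04, or 0.331), and the list was not called in the other comparisons (adjusted p = 0.866 and 0.318).

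The list of 17 plasma and B cell genes was not called in any comparison (adjusted p = 0.866, 0.153, 0.273 and 0.235). Of 159 genes of neurotransmitter receptor and ion channel families, 13 rose and 2 fell in aged against adult, while the family shifted down (median -0.14, adjusted p = 0.0258, or 0.763 with an estimated correlation, and 0.00620, or 0.713, without Grin2a, Gabra3 and Gabre). It rose in adult against adolescent (12 and 7, adjusted p = 1.06e-04, or 0.713, and 3.03e-04, or 0.713, without these genes) and adult against fetal (44 and 14, adjusted p = 0.00345, or 0.713), and was not called in adolescent against fetal (23 and 11, adjusted p = 0.545). These shifts go with raised receptor signal of adult replicates 2 and 3.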
